A study of Homo sapiens with 4 samples.

How the data were processed

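Gene expression and hashtag counts were measured in 1 pool of human myeloid cells by droplet single-cell RNA sequencing. Per the labels, the pool held microglia derived from WTC11, an established induced pluripotent stem cell line, and monocytes, monocyte-derived dendritic cells and monocyte-derived macrophages from donated blood. Each of the 4 cell types was kept with or without interferon beta, and each of these cultures carried its own hashtag, an antibody with an oligonucleotide barcode. The 8 hashtagged cultures were mixed and the mixture was loaded on 2 lanes. The labels list 2 gene expression libraries and 2 hashtag libraries, 1 of each per lane.

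The deposited matrix holds whole-number counts of unique molecular identifiers (UMIs) per feature and barcode for the whole pool, per the file headers and the values. The deposited barcode and feature lists hold names and identifiers, with no measurement of their own, per the file headers. The submitters' processing notes name Cell Ranger 3.0.2 and hg19. Per the labels, the authors processed each lane separately and then aggregated the lanes, and whether read depth was equalised in that step is not given in the sources used here. Of the gene identifiers, 99.8% are in GENCODE release 29, which is built on GRCh38, and 98.6% carry the same symbol there, so the build behind the counts was not settled between the notes and the feature list. Coordinates printed here are those of GENCODE release 29 on GRCh38, matched by gene identifier. Whether counting used strand is not given in the sources used here.

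The labels name hashtags 001 to 008 but do not say which hashtag marks which cell type or condition. Hashtags were therefore reported by number, no treated and untreated groups were formed, and ratios within a pair put the lower-numbered hashtag over the higher-numbered one. Each population is 1 culture, and the 2 lanes are 2 loadings of the same pool, so their spread is technical. No test across replicates was possible, and no p-value was computed. Intervals around counts (exact Poisson) and shares (exact binomial) are at the 95% level and cover counting error only.

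Lanes were read from the barcode suffix. Hashtags were assigned per lane with HTODemux in Seurat 5.3.0 under R 4.3.3, at a positive quantile of 0.99, and barcodes positive for more than 1 hashtag were left out as doublets. Cells were kept with at least 500 genes and at most 20% mitochondrial UMIs. Doublets of 2 cells with the same hashtag cannot be seen this way. A second score, from simulated doublets among the 30 nearest neighbours, was used only in an alternative.

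Kept cells were scaled to 10000 counts, log-transformed and clustered on 2000 variable genes, 30 principal components and 20 nearest neighbours with the Leiden method (leidenalg 0.10.2) at resolution 0.5. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The reported gene lists, mitochondrial, ribosomal protein and sex-linked genes were kept out of the variable genes. Counts were then summed per hashtag and lane and scaled to a common total per population (CPM). Correlations between profiles used genes outside the clustering with at least 10 CPM in at least 1 profile.

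A gene counted as higher or lower where at least 1 side had 50 or more UMIs in each lane and the log2 ratio of CPM + 1 was at least 1 in size with the same sign in both lanes. For every list and contrast, the genes eligible for naming were up to 2 with the largest ratio in each direction, and for covariation the 5 genes with the highest and up to 3 with the lowest correlation. These rules, the 12 gene lists and the marker lists were fixed before the data were examined. Genes were matched to the lists by symbol, so CGAS, listed under its older symbol MB21D1, was not counted as listed. Markers and genes named outside the rule were chosen after their values were seen. The plan called for contrasts between named cell classes. The marker rule did not give a microglia name to any population, so contrasts were made between pairs of hashtags by number, and pair 004/008 was set against the others because 5 of the 10 detected microglia markers were highest there, more than in any other pair. That choice was made after the data were seen.

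The core interferon-stimulated score was the share of UMIs in the 20 core genes after every cell was thinned to 2000 UMIs, the 10th percentile of kept cells with 1 hashtag rounded down to a multiple of 500, with shallower cells left out. Covariation was the Spearman correlation, across cells and within each lane, of each of the 219 other listed genes with that score. It was called at 0.2 in size with the same sign in both lanes, and set beside 1000 genes matched on mean expression. Among the 56 genes named within a pair, those with a ratio of one sign in both lanes of a pair and the opposite sign in both lanes of another were taken up for a closer look (12 genes, 1 of which is not reported here), and 0 listed genes were called higher in 1 pair and lower in another.

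The methods were tested on simulated data. For each of the 4 contrasts within a pair, Poisson counts were drawn with 200 changed genes. Of the 100 genes changed 3-fold, 100% were called in the right direction in the contrasts of 001 with 005, 002 with 006 and 004 with 008, and 99.0% in that of 003 with 007. All 100 genes changed 6-fold were called in each, and 0 unchanged genes were called among 7375 to 11333 tested. These draws held counting noise only, with no spread between cultures or cells and no free RNA, and the changed genes were abundant ones. They do not show how the calls behave between single cultures. For covariation over 2000 simulated cells, 6-fold changes in genes with a mean of at least 0.5 UMI were recovered for 100% of 11 genes, those from 0.1 to 0.5 UMI for 67.7% of 62, and those under 0.1 UMI for 0.787% of 127. Of 3200 cells drawn from the 8 profiles, 99.9% were in a cluster led by their own population. Each was drawn from the summed profile of its population, so spread within a population was not simulated.

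Alternatives covered the cell filter, the treatment of doublets, the variable genes, the resolution, leaving out each lane, size factors, pseudocounts of 0.5 and 5 CPM, the UMI floor, averaging over cells, thinning, the correlation threshold and a score of 5 genes. Those added after seeing the data were equal weight of both hashtags, cells in clusters led by their own hashtag, calls required in every pairing of single hashtags, covariation within a hashtag, and shares without the mitochondrial filter. Genes that show sex and genes with common whole-gene deletions were not reported.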

Results

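The study pooled 4 kinds of human myeloid cells, each with and without interferon beta, an antiviral cytokine, at 100 U/mL for 6 hours. Microglia, the resident macrophages of the brain, were derived from the WTC11 stem cell line. The dendritic cells were monocytes cultured for 5 days with GM-CSF and IL-4 (100 ng/mL each), the macrophages were monocytes cultured with GM-CSF (100 ng/mL), and the monocytes were fresh. The matrix held 64155 barcodes, with 8 hashtags counted beside the genes. The first lane gave 31721 barcodes and 294585378 UMIs, and the second lane 32434 barcodes and 296250678 UMIs. The median barcode had 7626 UMIs and 2406 genes.

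A single hashtag was assigned to 59.7% of barcodes (95% interval 59.3 to 60.1), more than 1 to 35.8% (35.5 to 36.2), and none to 4.46% (4.30 to 4.62). After the filters, 32190 cells with 1 hashtag were kept, between 2177 for hashtag 001 and 6852 for hashtag 003. Depth followed the hashtags: the median cell had 2411 UMIs in 001 and 2367.5 in 005, 6264 in 002 and 5591 in 006, 9434.5 in 003 and 9220.5 in 007, and 13379 in 004 and 16052.5 in 008. More than 20% mitochondrial UMIs were found in 37.1% of cells of hashtag 004 (35.7 to 38.6) and 23.7% of 008 (22.6 to 24.9). The share was 18% in 003, 18.9% in 007, and at most 2.21% in 001, 002, 005 and 006. Each population is 1 culture, the lanes are technical repeats of 1 pool, and the intervals cover counting error only.

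Marker genes divided the 8 populations into 4 pairs. S100A8, a calcium-binding protein of monocytes and neutrophils, stood at 912 CPM in hashtag 001 and 2429 CPM in 005, and at or below 63.8 CPM in the other 6. CD209, a lectin of dendritic cells, reached 266 CPM in 002 and 253 CPM in 006, against at most 24.2 CPM elsewhere. MARCO, a macrophage scavenger receptor, was highest in 003 at 85.2 CPM and 007 at 95.4 CPM, while 008 had 50.5 CPM. GPR34, a lysophosphatidylserine receptor of microglia, was at 94.2 CPM in 004 and 195 CPM in 008, above the 65.7 CPM of 007. Over 53 detected markers, every hashtag correlated best with its partner, with Pearson's r across genes of 0.894 for 001 and 005, 0.970 for 002 and 006, 0.969 for 003 and 007, and 0.962 for 004 and 008. Over 7966 genes not used in clustering, 002 and 003 correlated best with each other (r = 0.945), above 0.934 for 002 with 006 and 0.931 for 003 with 007. For the other hashtags the partner stayed the closest, at 0.956 for 001 with 005 and 0.929 for 004 with 008. The pairing of 002 and of 003 thus rests on the markers. These genes include the interferon lists and leave out the variable genes, so they may favour hashtags of like core score, which was not tested.

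Pair 001/005 was monocyte-like, with S100A8, S100A12 and VCAN among its 10 leading genes by fold, and 7 of 10 monocyte markers highest there. Pair 002/006 was dendritic cell-like, led by CCL18, CCL17 and CD209, with 10 of 12 dendritic cell markers highest there. The other pairs kept their numbers. Pair 003/007 was led by TM4SF19 and ALDH1A1 but also by the monocyte markers MNDA and FCN1, and pair 004/008 by FN1, MMP7, SPP1 and APOE together with the macrophage marker CHI3L1. Of the 10 detected microglia markers, 5 were highest in 004/008, and TMEM119, GPR34, SLC2A5 and BHLHE41 were above all other populations in both of its hashtags. P2RY12, a purinergic receptor of microglia, was at 5.57 CPM in 004 (4.84 to 6.37) and 0.391 CPM in 008 (0.258 to 0.569). The transcription factor SALL1 had 0 UMIs in all 8 populations, with upper counting limits from 0.0521 to 0.625 CPM. The C1Q genes of the same list were highest elsewhere, C1QB and C1QC in 002/006 and C1QA in 003/007. The macrophage markers divided, with 5 of 12 highest in 003/007, 5 in 004/008 and 2 in 002/006. Of markers of other cells, 4 of 5 detected T cell genes, 4 of 4 erythroid, 3 of 3 granulocyte and 2 of 4 B cell genes were highest in 002/006. In 001/005 this held for 3 of 4 natural killer cell genes, 4 of 5 stromal or endothelial and 1 of 1 progenitor gene, and in 003/007 for 1 of 1 platelet gene. The 3 plasmacytoid dendritic cell genes peaked in 001/005, 002/006 and 004/008, 1 in each.

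Clusters followed the hashtags. Of the kept cells with a hashtag, 94.1% lay in a cluster led by their own hashtag and 96.6% in one led by their own pair. By hashtag, the share in a cluster led by the own hashtag was 81.9% for 001 and from 92.0% to 98.2% for the others. The shares of pairs were 21.7% for 001/005, 20.4% for 002/006, 36.5% for 003/007 and 21.4% for 004/008, although equal numbers of cells from each culture were mixed per the labels. Several small clusters were led by genes of other cell types. Cluster 13, led by the cytotoxic and T cell genes GNLY, NKG7 and CD3D, made up 2.00% of 001/005 (1.69 to 2.36), 1.39% of 002/006 (1.12 to 1.70) and 0.554% of 003/007 (0.428 to 0.706), but 0.0145% of 004/008 (0.000367 to 0.0807). Cluster 17, led by the plasma and B cell genes JCHAIN and MS4A1 and the collagen gene COL3A1, ranged from 1.12% of 001/005 to 0.0290% of 004/008. Cluster 12, led by HBD and the granule genes MPO and ELANE, made up 2.69% of 001/005 and 0.246% of 004/008. Cluster 14, led by CCR7, made up 4.07% of 001/005 and at most 0.0761% of the others. Cluster 15, led by the cell cycle genes MKI67 and TOP2A, made up 2.13% of 003/007 (1.88 to 2.41), 0.420% of 004/008 (0.282 to 0.603) and at most 0.0609% of the others. Across the 7516 genes compared, 004/008 correlated with 003/007 at r = 0.888 (Spearman's rho 0.874), with 001/005 at 0.846 (0.799) and with 002/006 at 0.830 (0.803). Among the other pairs, r was 0.920 for 001/005 with 002/006 (rho 0.902), 0.899 for 001/005 with 003/007 (0.868) and 0.934 for 002/006 with 003/007 (0.916). Genes are not independent replicates.

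The first contrast asked how pair 004/008 differed from the monocyte-like pair 001/005. More lipid and scavenging genes were higher than lower in 004/008, and more inflammatory and class II genes lower than higher. APOE, the main apolipoprotein of brain lipid transport (ENSG00000130203, chromosome 19, 44905754 to 44909393), was at 14947 CPM against 1350 CPM, a log2 ratio of 3.47 (3.38 and 3.59 in the lanes). Its level in 001 and 005 was 9.90% and 8.63% of that in 004/008. No ratio was corrected for free RNA shared between droplets, which can take a larger share of the counts of shallow cells, such as those of 001 and 005, and so move a ratio in either direction. TREM2, a lipid-sensing receptor (ENSG00000095970, chromosome 6, 41158506 to 41163186), was at 547 CPM against 63.9 CPM, a log2 ratio of 3.08 (2.90 and 3.30). EREG, an epidermal growth factor family ligand, had a log2 ratio of -7.38 and the neutrophil chemokine CXCL8 one of -6.43.

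By list, 12 of 28 lysosome and lipid genes were higher and 3 lower, with APOC1 at 3.42, APOC2 at 3.4 and LGALS3, which encodes a galectin, at -2.45. Of 13 tested scavenging and efferocytosis genes, 7 were higher and 0 lower, led by PROS1 at 2.41 and ITGB5 at 2.36. Of 42 tested genes at Alzheimer disease risk loci, 9 were higher and 7 lower, LILRB2 (-3.71) and the cholesterol exporter ABCA1 (-1.75) among the latter. Of 14 class II and costimulation genes, 7 were lower, including CCR7 at -5.32, which also leads cluster 14 (4.07% of 001/005 and 0.0435% of 004/008), and HLA-DPB1 at -2.76, and CD40 was higher at 1.56. Only 4 of these 7 also had fewer UMIs per cell in 004/008. HLA-DPB1 had 2.57 and 2.43 UMIs per cell in 001 and 005 and 2.43 and 1.89 in 004 and 008, against 20.2 to 22.9 in the other 4 hashtags, so its ratio may follow cell depth and free RNA. Of 20 inflammatory genes, 12 were lower, while IL18 (2.29) and CSF1 (2.23) were higher. Complement divided, with C2 at 1.69 against CFP at -6.38 and CFD at -3.45, and 5 of 12 genes higher and 3 lower. Of 15 pattern recognition genes, 6 were lower, led by CLEC4E at -3.85 and AIM2 at -2.52. Proliferation genes were 1 higher (CCNB2, 1.58) and 1 lower (NUSAP1, -1.33) of 13.

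Because the profile of a pair sums both hashtags, its interferon lists also follow how many UMIs each hashtag gave. Kept cells gave 38069930 UMIs in 004 and 68994216 in 008, but 5898172 in 001 and 12802291 in 005. The hashtag of higher core score thus weighs somewhat more in 004/008 (004) than in 001/005 (001). That alone raises, and does not lower, the summed level of interferon genes in 004/008. Of 20 core genes, 6 were lower and 1 higher, with RSAD2 at -5.48, CMPK2 at -4.27 and IFI6 at 1.38. Of 30 other interferon-stimulated genes, 9 were lower, APOBEC3A at -5.97 and GBP4 at -2.81 among them, and IFI27 was higher at 1.10. Of the 10 interferon-induced chemokines and cytokines, 5 were lower, including CXCL11 at -2.96 and CXCL9 at -1.86. Of 15 receptor and signalling genes, 7 were lower, led by SOCS3 at -2.36 and IRF9 at -1.82. Fewer UMIs per cell in 004/008 were found for 2 of the 6 lower core genes, 3 of the 9 other interferon-stimulated genes, 1 of the 5 chemokines and cytokines and 0 of the 7 receptor and signalling genes. In all, 39 listed genes were higher and 66 lower of 232 tested, while of all 12097 genes tested 2013 were higher and 1271 lower. Of the 66 lower listed genes, 26 also had fewer UMIs per cell in 004/008, a comparison made after the values were seen, and the deeper cells of 004/008 favour more UMIs per cell there. When the call had to hold in every pairing of single hashtags, 21 listed genes were higher and 29 lower, and APOE, TREM2, RSAD2, CMPK2 and APOBEC3A were among them while IFI6 was not. In 005, RSAD2 had 0.295 UMIs per cell, CMPK2 0.0578 and APOBEC3A 0.185. The values were 0.603, 0.0938 and 0.235 in 004, and 0.370, 0.0709 and 0.167 in 008. The calls of these genes against 005 may therefore follow cell depth and free RNA. Some pairings set a hashtag of high core score against one of low score. They push genes that follow the score in opposite directions, which makes such a call less likely. Without doublet removal 13 listed genes were higher, and 19 with doublets removed by their score.

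Against the dendritic cell-like pair 002/006, most class II and costimulation genes were lower in 004/008. HLA-DRA, the class II alpha chain, was at 529 CPM in 004/008 and 13399 CPM in 002/006, a log2 ratio of -4.66 (-4.67 and -4.65). In that list 10 of 14 genes were lower and 0 higher, HLA-DPB1 at -4.76 among them. APOE (4.42), the matrix protein and cytokine gene SPP1 (4.40) and APOC1 (4.25) were higher, and their levels in 002 and 006 were from 4.66% to 5.35% of those in 004/008. Of 42 tested Alzheimer risk-locus genes, 12 were higher, including ABI3 at 2.62, and 7 lower, including MS4A6A at -2.89 and ACE at -2.60.

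Of 28 lysosome and lipid genes, 10 were higher and 4 lower, with LGALS3 at -2.06 and the fatty acid receptor CD36 at -1.52. Of 13 tested scavenging genes, 8 were higher, including CD300A at 3.36 and the efferocytosis receptor MERTK at 2.54, and GAS6 (-3.68) and STAB1 (-2.83) were lower. Complement had 3 genes higher and 4 lower of 12, with C3 at 3.49, C5AR1 at 1.77, CFD at -3.62 and CFP at -2.47. Of 18 tested inflammatory genes, 6 were higher, including CCL5 at 3.33 and IL1B at 2.71, and TNF (-2.92) and EREG (-2.63) were lower. Of 15 pattern recognition genes, TMEM173 (1.68) and TLR2 (1.62) were higher, and CLEC4A (-2.46) and TLR4 (-1.49) lower. Of 14 tested proliferation genes, 7 were lower, with NUSAP1 at -2.46 and TOP2A at -2.45. Without cells outside clusters led by their own hashtag, the TOP2A ratio was 0.12 and the NUSAP1 ratio -1.61. Cluster 15, led by cell cycle genes, made up 0.0609% of 002/006 and 0.420% of 004/008, and cluster 12, with HBD and MPO among its leading genes, 1.77% and 0.246%, and whether few cells account for the lower list was not tested.

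Of 20 core interferon-stimulated genes, 9 were lower and 1 higher in this contrast, with RSAD2 at -4.69, CMPK2 at -4.64 and IFI6 at 1.25. Kept cells gave 38069930 UMIs in 004 and 68994216 in 008, but 23326195 in 002 and 16836401 in 006. The hashtag of higher core score thus weighs less in 004/008 (004) than in 002/006 (002). That alone lowers the summed level of interferon genes in 004/008. An alternative, added after seeing the data, gave both hashtags equal weight. It left the counts of all higher and lower listed genes much the same, with 46 higher against 44. Counts for the interferon lists alone are not given for it, so the part of the weighting in these calls stays open. Of 30 other interferon-stimulated genes, 10 were lower, led by APOBEC3A at -4.55 and RTP4 at -1.88. CCL7 (3.68) and CCL2 (1.94) were higher and TNFSF10 (-1.32) lower among the 10 induced chemokines and cytokines. Of 15 receptor and signalling genes, 6 were lower, with SOCS1 at -2.18 and IRF5 at -1.85. In all, 44 listed genes were higher and 64 lower of 231 tested, against 1662 and 1234 of all 12191 genes tested. Of the 64 lower, 46 also had fewer UMIs per cell in 004/008. In every pairing of single hashtags 25 and 26 listed genes were called, with 0 of the core genes, 0 of the other interferon-stimulated genes and 0 of the induced chemokines and cytokines. Here too, the pairings of 004 with 006 and 008 with 002 push genes that follow the core score in opposite directions. The counts of 0 for these lists therefore say little. Without doublet removal, 23 listed genes were higher.

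Pair 003/007 had the highest correlation with 004/008, but pair 001/005 did without doublet removal (r = 0.941 against 0.927) and with doublets removed by their score (0.909 against 0.895). Against 003/007, 20 listed genes were higher and 53 lower of 234 tested, while of all 12543 genes tested 1247 were higher and 899 lower. APOE (log2 ratio 4.03, lanes 4.05 and 4.02) and SPP1 (4.33, lanes 4.29 and 4.36) were again higher, and HLA-DRA (-4.25) and LGALS3 (-3.12) lower. Of 28 lysosome and lipid genes, 5 were higher, APOC1 at 3.10 among them, and 6 lower, including LAMP1 at -1.79. Of 14 class II genes, 8 were lower and 0 higher, with HLA-DPB1 at -3.87. Of 42 tested risk-locus genes, ABI3 (1.53) and 3 others including APOE were higher, and 5 were lower, including LILRB2 (-2.45) and ACE (-2.17).

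Scavenging genes were 6 higher and 3 lower of 13, with CD300A at 2.53 and the phagocytic bridge gene MFGE8 at 2.19, against GAS6 at -2.65 and STAB1 at -1.78. C3 was higher at 2.20 and CFD lower at -3.11, and the other 10 complement genes were neither. Of 20 inflammatory genes, CCL5 (2.94) and IL1B (1.10) were higher, and 5 were lower, including TNF (-3.14) and CXCL5 (-2.50). Pattern recognition genes were 4 lower of 15, with CLEC4E at -2.80 and AIM2 at -1.44, and proliferation genes 7 lower of 15, with MKI67 at -2.31 and RRM2 at -2.18. Both of these lead cluster 15, which made up 2.13% of 003/007 and 0.420% of 004/008. Whether these few cells account for the lower list was not tested. Of 20 core genes, 8 were lower, with RSAD2 at -5.16 and CMPK2 at -4.69, and IFI6 was higher at 1.34. Kept cells gave 70860142 UMIs in 003 and 49033104 in 007, but 38069930 in 004 and 68994216 in 008. The hashtag of higher core score, 003 or 004, thus weighs less in 004/008. Equal weight of both hashtags left the counts of all higher and lower listed genes much the same here too. Counts for the interferon lists alone are not given for it, so the part of the weighting in the interferon calls stays open. Of 30 other interferon-stimulated genes, 3 were lower, with APOBEC3A at -5.30 and GBP4 at -2.09. Of the 10 induced chemokines and cytokines, CCL7 was higher at 1.14, and 3 were lower, IL27 (-1.87) and CXCL11 (-1.71) among them. Of 15 receptor and signalling genes, 0 were called. In every pairing of single hashtags, 10 listed genes were higher and 22 lower, and 0 genes of these 4 interferon lists were called, RSAD2, CMPK2, APOBEC3A and IFI6 included. The pairings of 004 with 007 and 008 with 003 cross high and low core scores, so these 0 calls were largely set by the check. RSAD2 was at 43.4 CPM in 004 and 1835 CPM in 003, but at 22.3 CPM in 008 and 32.0 CPM in 007.

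**Figure D1:**
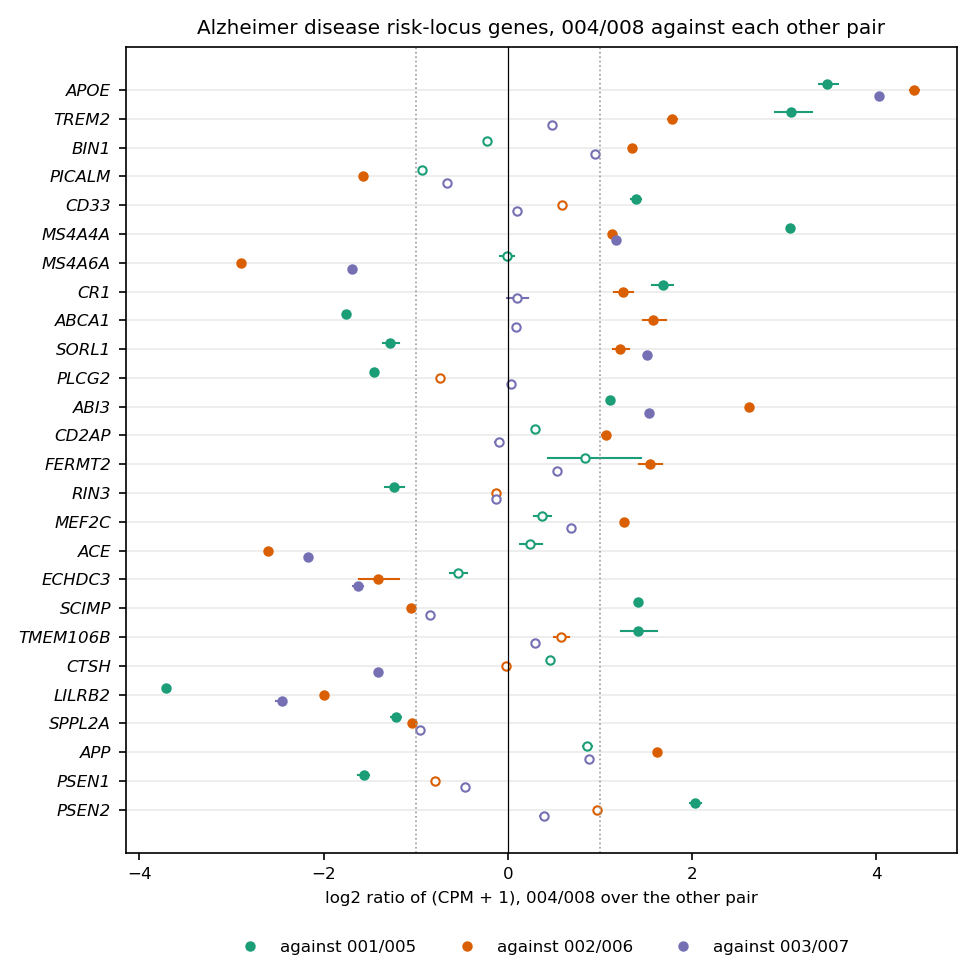
Log2 ratios of CPM + 1 (horizontal axis) of pair 004/008 over each of the other pairs (colours), for the Alzheimer disease risk-locus genes called in at least 1 contrast (rows). Points give both lanes together, lines join the lanes, filled points were called, dotted lines mark log2 ratios of -1 and 1, and APOE lies at 3.47, 4.42 and 4.03.

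Within each pair, the lower-numbered hashtag had the higher level of the core interferon-stimulated genes. Thinned to 2000 UMIs per cell, the median cell had 4.40% of its UMIs in these genes in hashtag 001, 3.05% in 002, 3.05% in 003 and 2.85% in 004. The medians were 0.25% in 005, 0.15% in 006, 0.10% in 007 and 0.35% in 008. In 005, 006 and 007, ISG15 had 2.91, 3.13 and 3.62 UMIs per cell and CXCL10 1.54, 1.52 and 1.63. Median depth rose from 2367.5 UMIs in 005 to 9220.5 in 007. IFI6 rose with it, from 0.834 to 1.90, and ISG15 reached 9.66 in 008. Free RNA may set part of these low levels. Their order, and the sizes of ratios compared between pairs, may therefore follow cell depth, which was not tested. Without thinning, they were 4.40%, 3.03%, 3.07% and 2.89% for 001 to 004, and 0.251%, 0.135%, 0.0990% and 0.338% for 005 to 008. Thinning left out 528 cells of 001 and 1214 of 005 as shallower, and between 15 and 93 of each other hashtag.

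**Figure D2:**
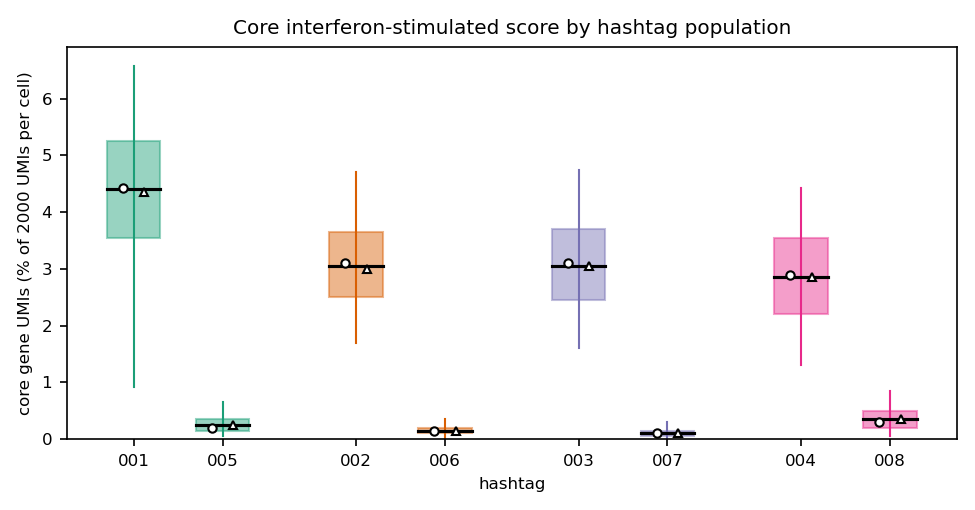
Percent of each cell's 2000 thinned UMIs in the 20 core interferon-stimulated genes (vertical axis) by hashtag, in pairs by colour. Bars are medians, boxes the 25th to 75th percentiles over cells, lines the 5th to 95th, and the circle and triangle the medians of the first and second lane, with medians from 2.85 to 4.40 in 001 to 004 and from 0.10 to 0.35 in 005 to 008.

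All 20 core genes were higher in 001 than 005, in 002 than 006 and in 003 than 007, and 17 of 20 in 004 than 008. RSAD2, the antiviral enzyme viperin (ENSG00000134321), had the largest core ratio in the first 3 pairs, with log2 ratios of 5.20, 4.82 and 5.80. In 004 against 008 the largest were those of IFIT2 (4.90) and IFIT1 (4.62), which encode RNA-binding antiviral proteins. The 3 core genes not called there were RSAD2 (0.93), IFI6 (0.63) and CMPK2 (0.55). RSAD2 was at 43.4 CPM in 004 (41.4 to 45.6) and 22.3 CPM in 008 (21.2 to 23.4), against 4120 CPM in 001, 1335 CPM in 002 and 1835 CPM in 003. CMPK2, a mitochondrial nucleotide kinase, was at 6.75 CPM in 004 and 4.28 CPM in 008, against 254 to 327 CPM in 001 to 003. IFI6 differed in another way, at 3207 CPM in 004 and 2067 CPM in 008, against 168 to 313 CPM in 005 to 007.

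The other interferon-stimulated genes were called higher for 27 of 28 tested in 001 against 005, 30 of 30 in 002 against 006, 29 of 30 in 003 against 007 and 29 of 30 in 004 against 008. APOBEC3A, a cytidine deaminase (ENSG00000128383), had log2 ratios of 5.16, 4.45 and 5.85 in the first 3 pairs and 0.69 in 004 against 008, at 16.9 CPM and 10.1 CPM. ISG20 had ratios of 4.07, 4.69 and 4.72 in 001 against 005, 002 against 006 and 004 against 008. Of the induced chemokines and cytokines, 10 of 10, 8 of 9, 10 of 10 and 10 of 10 were higher in the order of the pairs. CXCL11 (5.76) and CCL7 (4.51) led in 001, TNFSF10 (4.84) and CCL8 (4.17) in 002, CCL8 (5.87) and CXCL10 (5.59) in 003, and CXCL10 (5.67) and CCL8 (5.16) in 004. Receptor and signalling genes were 1, 3, 4 and 5 higher of 15. JAK2 had a ratio of 2.15 in 001, IRF1 one of 2.41 in 002, 2.42 in 003 and 3.66 in 004, and SOCS1, a feedback inhibitor, one of 4.15 in 004. IFNGR1 was lower in 002 (-1.02) and 003 (-1.72).

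**Figure D3:**
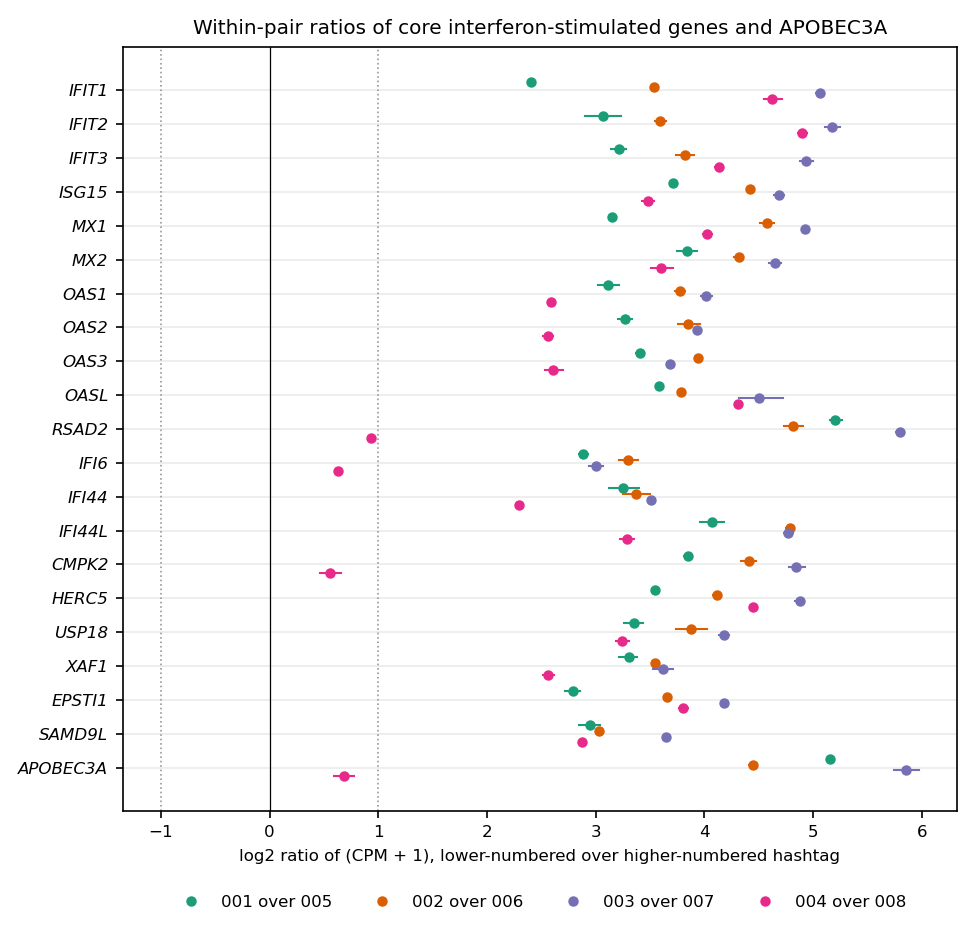
Log2 ratios of CPM + 1 (horizontal axis), lower-numbered over higher-numbered hashtag, for the 20 core interferon-stimulated genes and APOBEC3A (rows) in the 4 pairs (colours). Points give both lanes together, lines join the lanes and dotted lines mark -1 and 1, and RSAD2, IFI6, CMPK2 and APOBEC3A lie between 0.55 and 0.93 for 004 over 008.

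Within pairs, Alzheimer risk-locus genes were 1 higher and 3 lower of 34 tested in 001 against 005, 3 and 0 of 38 in 002 against 006, 4 and 0 of 42 in 003 against 007, and 3 and 0 of 41 in 004 against 008. Over all genes tested, the numbers in this order were 290 and 79 of 7409, 458 and 301 of 8932, 543 and 356 of 10868, and 704 and 189 of 11372. Whether the list differs from all genes was not tested. CD2AP, an actin adaptor (ENSG00000198087), was higher in all 4 lower-numbered hashtags, with log2 ratios of 1.82 in 001, 1.76 in 002 and 2.03 in 003, and levels of 87.7 CPM in 004 against 32.9 CPM in 008. SCIMP, a transmembrane adaptor (ENSG00000161929), was higher in 002 (2.30), 003 (2.86) and 004 (2.27), and at 44.8 CPM in 001 (39.5 to 50.5) against 34.4 CPM in 005 (31.2 to 37.7). MS4A6A (ENSG00000110077) was higher in 004 than 008 by 2.15 (lanes 2.21 and 2.10), at 173 CPM against 38.1 CPM. Its ratio was 0.48 in 001, -0.25 in 002 and 0.46 in 003, and the difference between pairs was not tested. SORL1, an endosomal sorting receptor, was lower in 001 than 005 (-1.77), as was ABCA1 (-1.13).

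Among the other lists, AXL, a receptor for dying cells, was higher in each lower-numbered hashtag, with ratios of 2.07, 2.94, 3.39 and 2.46. So were AIM2, a sensor of cytosolic DNA (2.71, 2.40, 2.83 and 2.05), and the interleukin antagonist IL1RN, at 1.99 in 001, 3.17 in 003 and 3.01 in 004 among those named by the rule. SERPING1, the complement inhibitor, had ratios of 2.63, 3.23 and 3.45 in 001, 002 and 003, and MYD88 1.16, 2.40 and 1.5. IL1A (-2.79) and IL1B (-2.58) were lower in 001 than 005, CXCL3 (-2.06) and CXCL2 (-1.81) in 003 than 007, and CXCL8 (-1.48) in 004 than 008. Inflammatory genes as a list were 1 higher and 3 lower of 19, 3 and 0 of 13, 2 and 5 of 17, and 3 and 1 of 18, with IL6 at 2.18 in 004 and TNF at 1.43 in 002. EREG was higher in 002 (2.64) and 003 (1.85).

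Class II and costimulation genes were 0, 3, 2 and 4 higher of 12, 14, 13 and 12 tested, with 0 lower in each pair. CD80 had ratios of 1.93 in 002 and 1.98 in 003, CD40 1.24 and 1.18, and in 004 CIITA, the class II transactivator, one of 2.01 and IFI30 one of 1.67. Complement genes were 1 higher in each of the first 3 pairs and 4 in 004, with C2 at 1.99 there, and C3 was lower in 003 (-1.10). Pattern recognition genes were 2, 3, 3 and 4 higher of 13, 13, 15 and 15, with TLR7 at 2.13 in 004, TLR5 at -2.02 in 002 and -1.34 in 003, CLEC4A at -1.11 in 002 and TLR6 at -1.02 in 003. These counts leave out CGAS, listed under its older symbol, which was higher in each pair (1.54, 1.58, 1.75 and 2.67). Scavenging genes were 2, 1, 1 and 2 higher, with CD163 at 1.21 in 001 and TIMD4 at 2.42 in 004. ITGAV was lower in 001 (-1.10) and 002 (-1.38), and SCARB1 in 002 (-1.81). Lysosome and lipid genes were called for CTSL (1.13 in 001), PLIN2 (-1.54 in 003) and ABCG1 (-1.16 in 003), and 0 of 26 tested in 002 and 0 of 27 in 004. Proliferation genes were called for 0 of 2 tested in 001, 0 of 9 in 002, 0 of 15 in 003 and 3 of 10 in 004, where TOP2A (1.74) and NUSAP1 (1.46) were higher, at 4.86 CPM and 3.68 CPM. Cluster 15, led by cell cycle genes, held 29 cells of 004 and 0 of 008, and the difference between pairs was not tested.

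In all, 66 listed genes were higher and 7 lower in 001 against 005, 75 and 5 in 002 against 006, 76 and 11 in 003 against 007, and 84 and 1 in 004 against 008. The lists hold many interferon genes. Over all genes tested, the numbers were 290 and 79 of 7409, 458 and 301 of 8932, 543 and 356 of 10868, and 704 and 189 of 11372. Of 7151 genes tested in all 4 pairs, 195 were higher in each lower-numbered hashtag, where 0.0543 would be shared by independent lists of these sizes. Lower in each was 1 gene, SLC16A6 (-1.17, -1.53, -2.03 and -1.34), against 0.000256 by the same reckoning, and it was named after its values were seen. The 4 contrasts come from 1 pool, and their log2 ratios correlated at r = 0.711 to 0.896 across genes. The lists are therefore not independent, and the expected numbers give a scale and no test. Median-of-ratios scaling moved all log2 ratios by 0.15 in 001 against 005, 0.31 in 002 against 006, 0.33 in 003 against 007 and 0.17 in 004 against 008. Without doublet removal, 42 listed genes were higher in 001 against 005. The number of lower listed genes moved with the processing, from 4 to 24 in 003 against 007.

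Covariation across the cells of a pair, which holds both of its hashtags, was measured against the core score. Of 219 listed genes outside the core, 37 correlated with the core score in 001/005, 39 in 002/006, 41 in 003/007 and 39 in 004/008. Of 1000 matched genes, 27, 33, 37 and 32 did. Each pair joins a hashtag of high and one of low core score, so abundant genes that differ between the 2 correlate for that reason. The 219 genes include interferon lists, while the matched genes hold no listed gene. The comparison therefore largely repeats the contrast within the pair. TNFSF10, which encodes the death ligand TRAIL, led in 002/006 (mean rho 0.770), 003/007 (0.765) and 004/008 (0.738), and APOBEC3A in 001/005 (0.733). The other leading genes were TNFSF10 (0.715), ISG20 (0.701), LY6E (0.682) and SAMD9 (0.653) in 001/005, and ISG20 (0.712), SAMD9 (0.658), LY6E (0.634) and CXCL10 (0.624) in 002/006. In 003/007 they were CXCL10 (0.759), CCL8 (0.694), APOBEC3A (0.688) and ISG20 (0.641), and in 004/008 TNFSF13B (0.650), CXCL10 (0.626), ISG20 (0.619) and GBP1 (0.607).

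Anticorrelated genes were 0, 1, 2 and 4 of 219, against 42, 60, 41 and 7 of the 1000 matched genes. CLEC4A (-0.258) was called in 002/006, and IFNGR1 (-0.279) and the fatty acid-binding protein gene FABP5 (-0.267) in 003/007. In 004/008 the lowest were LPL (-0.282), SPP1 (-0.279) and FABP5 (-0.244), with CD63 (-0.221) also called. Within single hashtags, 23 genes correlated in 001, 18 in 002, 13 in 003 and 17 in 004, but 0 in 005, 006 and 007 and 3 in 008. The score of 005 to 007 had a 95th percentile of at most 0.65% of 2000 UMIs, so counting noise may hide correlations there, and the counts cannot be set against those of 001 to 004. Of the 1000 matched genes, 18, 16, 13 and 16 did in 001 to 004, and 0 in each of the others. Without thinning, 65 genes correlated and 10 anticorrelated in 004/008, and with a threshold of 0.3 in size 0 anticorrelated in any pair. Simulated 6-fold changes were recovered for 0.787% of genes under 0.1 UMI per cell.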

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

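All results here were picked out after the data were seen, by a ratio of one sign in both lanes of 1 hashtag pair and the opposite sign in both lanes of another, and the differences between pairs were not tested. The rule asks for no size, so several of the ratios lie near 0. Among genes higher in 004 than 008, MS4A6A had a log2 ratio of 2.15 there and -0.25 in 002 against 006, the class II transactivator CIITA 2.01 and -0.61 in 002 against 006, and IFI30 1.67 and -0.17 in 001 against 005. The complement gene C2 (1.99) was higher in 004 as well, with -0.29 in 002 against 006. The cell cycle genes TOP2A (1.74) and NUSAP1 (1.46) had ratios of -1.06 and -0.81 in 003 against 007. EREG had 2.64 and TNF 1.43 in 002 against 006, and -0.40 and -0.087 in 001 against 005. CCL7 had 4.51 in 001 against 005 and -0.51 in 002 against 006. ABCA1 had 0.35 in 003 against 007 and -1.13 in 001 against 005, and ITGAV 0.088 in 004 against 008 and -1.38 in 002 against 006.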

How the results depend on the processing

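The alternatives chosen after seeing the data were equal weight of the hashtags, cells in clusters led by their own hashtag, every pairing of single hashtags, covariation within a hashtag and shares without the mitochondrial filter. Where values moved, the cause was not tested. One named ratio changed sign: TOP2A in 004/008 against 002/006 was -2.45 and became 0.12 in cells of clusters led by their own hashtag. Equal weight, no low-count filter, a filter of 200 UMIs and the score of 5 genes moved no count by more than 1.5 times. The resolution of 1.0 changes clusters but no value per hashtag, and the variable genes enter those values through the correlations alone. No paired analysis was possible because the lanes carry the same pool and no test was made. Counts set the depth limit, as genes under 50 UMIs in a lane on both sides gave no call.

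Pearson's r is given for 001/005 with 002/006, 001/005 with 003/007, 001/005 with 004/008, 002/006 with 003/007, 002/006 with 004/008 and 003/007 with 004/008, in this order. It was 0.907, 0.886, 0.828, 0.928, 0.818 and 0.885 with 1000 variable genes, and 0.874, 0.843, 0.786, 0.907, 0.775 and 0.857 with a floor of 50 CPM. Over all genes it was 0.859, 0.844, 0.770, 0.913, 0.794 and 0.872. With at least 1000 genes and at most 10% mitochondrial UMIs it was 0.930, 0.906, 0.857, 0.940, 0.848 and 0.896. With the expected share of highest doublet scores removed in place of hashtag doublets it was 0.940, 0.945, 0.909, 0.932, 0.828 and 0.895. Without doublet removal it was 0.972, 0.969, 0.941, 0.963, 0.900 and 0.927. A pseudocount of 5 CPM gave 0.928, 0.908, 0.867, 0.944, 0.860 and 0.909. A pseudocount of 0.5 CPM moved the first to 0.918 and the last 3 to 0.932, 0.821 and 0.882. With report lists not held out, the first was 0.926, the third 0.853 and the last 2 were 0.829 and 0.889. Leaving out a lane gave 0.918 to 0.919 for 001/005 with 002/006, 0.838 to 0.851 for 001/005 with 004/008 and 0.827 to 0.830 for 002/006 with 004/008.

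The shares of 001/005, 002/006, 003/007 and 004/008 were 15.4%, 24.0%, 42.2% and 18.5% with the stricter cell filter, 23.8%, 19.7%, 34.5% and 22% with doublets removed by score, 22.8%, 19.4%, 35.0% and 22.8% without doublet removal, and 20.3%, 19.2%, 36.3% and 24.3% without the mitochondrial filter.

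The difference in median core score was 4.00 for 001 minus 005, 3.0 for 003 minus 007 and 2.65 for 004 minus 008 with the stricter filter. It was 3.5 for 001 minus 005 and 3.0 for 003 minus 007 with doublets removed by score, and 2.95, 2.75, 2.85 and 2.20 for the 4 pairs without doublet removal. Leaving out a lane gave 2.95 to 3.0 for 003 minus 007 and 2.50 to 2.60 for 004 minus 008.

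For listed genes, every pairing of single hashtags left 21, 25 and 10 higher and 29, 26 and 22 lower in 004/008 against 001/005, 002/006 and 003/007. Without doublet removal, 13 were higher against 001/005, 23 against 002/006 and 42 in 001 against 005, while 3 were lower in 002 against 006, 4 in 003 against 007 and 0 in 004 against 008. With doublets removed by score, 19 were higher against 001/005, and 20 were lower in 003 against 007 and 0 in 004 against 008. In clusters led by their own hashtag, 24 were lower in 003 against 007 and 2 in 004 against 008. Median-of-ratios scaling gave 4, 3 and 7 lower genes in the first 3 pairs. A pseudocount of 5 CPM gave 3 lower in 002 against 006 and 6 in 003 against 007. In 004 against 008, a pseudocount of 0.5 CPM gave 4 lower and the mean of each cell's CPM 2. Leaving out a lane gave 2 to 3 lower in 004 against 008 and 6 to 8 in 002 against 006.

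Anticorrelated genes in 001/005, 002/006, 003/007 and 004/008 numbered 1, 2, 6 and 10 without thinning and 5, 5, 10 and 8 with a threshold of 0.1, and with one of 0.3 they were 0 in the last 3. Correlated genes in 004/008 numbered 65 without thinning. With a threshold of 0.1 they were 56 in 001/005, 62 in 002/006 and 67 in 004/008. Leaving out a lane gave 0 to 2 anticorrelated in 001/005.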

Other observations

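All tests in this part were chosen after the result was seen, except the share of cells with a UMI of genes led by 004/008, which was fixed before it was computed. Within hashtag 004, 7 of 28 genes of lysosome and lipid handling varied against the core score. SPP1 had a mean rho of -0.434 (lanes -0.435 and -0.433), CD63 -0.368, CD9 -0.331, the lysosomal lipase gene LIPA -0.293 and LPL, lipoprotein lipase, -0.290. FABP5 (-0.237) and GPNMB (-0.233) were called as well. In 003, FABP5 and LPL were anticorrelated, but CTSB (0.362) and PSAP (0.215) of the same list correlated with the score, and in 002 6 genes of the list did, led by CTSB (0.504) and CTSL (0.331), and 0 were anticorrelated. Cells of 004 were divided between cluster 9 (47.8%), with CXCL10 among its 10 leading genes, and cluster 10 (45.4%), and covariation within a cluster was not measured. CXCL10 (0.571) and TNFSF10 (0.445) had the highest correlations in 004, and MS4A6A, at an Alzheimer risk locus, had 0.363.

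Of the 195 genes higher in all 4 lower-numbered hashtags, 137 matched no list by symbol. CGAS was 1 of these 137, although its older symbol MB21D1 is on the pattern recognition list. ETV7, HES4 and NEXN were among those with the highest lowest ratio, 3.17, 3.15 and 3.13. Genes with at least 4-fold higher levels in 1 pair alone and less than 2-fold change in both lanes of the others were few: MYOF in 002 against 006 (2.74), and CH25H (2.38), NUDCD1 (2.22) and MS4A6A (2.15) in 004 against 008. The difference between pairs was not tested. CH25H was at 341 CPM in 004 and 64.7 CPM in 008, but at 6.65 to 18.6 CPM elsewhere. Free RNA could hide a change of CH25H in those other pairs. IFI6 had 34.3 UMIs per cell in 008 and 44.5 in 004, against 0.834 to 1.90 in 005 to 007.

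Genes led by 004/008 appeared in all other populations. For the 9 genes with at least 500 CPM in 004 and 008 and 4-fold lower levels elsewhere, SPP1, APOE and CHI3L1 among them, the median level in other hashtags was from 5.18% to 10.8% of that in 004/008. Doublets that escaped the hashtags are argued against as the whole source, since at least 99.9% of cells in each population carried a UMI of these genes. Free RNA from 004/008 cells is a candidate explanation, because 1 source keeps its genes in 1 ratio. The SD across genes of the log2 ratio was 0.44 in the median population. The 4-fold rule had already left out genes with higher levels in other populations. That limits the SD in advance, so a low value cannot decide for free RNA. The SD was above 0.5 in 003 (0.53) and 007 (0.63). There APOC1 stood at 11% and 12.6% and FN1 at 3.10% and 3.4%, so expression by those cells stays open. APOE had 4.01, 4.43, 3.44 and 4.09 UMIs per cell in 001, 002, 005 and 006, and 8.71 and 10.2 in 003 and 007.

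RSAD2, CMPK2 and APOBEC3A were low in hashtag 004, 30.7-fold, 37.6-fold and 31.3-fold below the lowest of 001, 002 and 003, which would be larger if part of the counts in 004 is free RNA and other cells hold as much of it. A low interferon-stimulated level of 004 as a whole is argued against, since the other 18 core genes had a median log2 ratio of -0.13 to the median of 001 to 003. So are too few counts, with the highest upper counting limit at a log2 ratio of -4.86, and reads lost in the annotation, since the genes reached at least 254 CPM in 001 to 003. RSAD2 and CMPK2 overlap by 830 bp on opposite strands of chromosome 2, but APOBEC3A lies on chromosome 22. The origin of the cells may account for the gap and cannot be told apart from the cell type, because the pool held 0 cultures of a second origin per cell type. The labels also do not say which cell type or origin hashtag 004 marks. The UMIs per cell in 004 were 0.603 for RSAD2, 0.0938 for CMPK2 and 0.235 for APOBEC3A, against 0.270 to 0.370, 0.0578 to 0.0813 and 0.135 to 0.185 in 005 to 008.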
